A study of Mus musculus with 11 samples.

How the data were processed

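CAGE tags were counted in 11 cortex libraries, 1 per group, and the samples were grouped by the labels: naive, and the infarcted or non-infarcted side at 7 d, 7 d with levetiracetam (LEV), 1 m, 1 m with LEV and 2 m after withdrawal of LEV. The study's design text gives another start of treatment and 1 week of withdrawal, and the labels, with LEV at 7 d and 2 weeks of withdrawal, were followed. Ages of 8–10 and 65–85 weeks are in the design text and are not given per library. The deposited values are CPM, tags scaled to the total of each library, of 22377 genes, made by the authors from their own alignments. The submitters' processing notes name BWA 0.7.17, HISAT2 2.0.5, DESeq2 1.20.0 and GRCm38, without stating what each was used for.

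Every CPM value is a whole number of tags divided by a library total, within 0.01 of a tag, so the tags were recovered. Library totals in tags are 12928291 for naive and, infarcted then non-infarcted, 16590924 and 17986333 at 7 d, 17257308 and 18810094 at 7 d with LEV, 13925503 and 13769133 at 1 m, 19208153 and 21000367 at 1 m with LEV and 17545291 and 16473888 at 2 m. The 10 highest genes hold 4.44% to 5.85% of the tags, and 3 tags, the floor for a ratio, are 0.143 to 0.232 CPM. Gene identifiers were matched without their version to GENCODE M21, which holds 22335 of them (99.8%), 22334 on the same strand. Overlapping genes can hold the same tags: 1133 genes with at least 20 tags have counts within 5% of those of a neighbour within 5 kb in every library, taken here as shared, and 79 carry a duplicated symbol.

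Log2(CPM + 1) values of genes with a mean CPM of at least 1 in the libraries compared were tested with limma 3.58.1 (moderated t, mean-variance trend) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg. A gene is called at adjusted p < 0.05. The side was tested over 5 states with state as a factor (4 residual degrees of freedom), each side against the 1 naive library (4), and time and LEV on each side and on the side difference over 7 d and 1 m with both factors (1). A log2 difference is the mean over states. The 2 m libraries enter the side and naive tests and are otherwise compared as single libraries, by ratios with exact 95% intervals on tags.

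Gene lists of cell types, inflammation, matrix, myelin, neuronal and synaptic genes, firing, stress, hormone, clock, sterol and neighbouring tissues were fixed before the data were examined, as were the comparisons, most alternatives and the rule for named genes. Lists were tested by camera with a preset correlation of 0.01, again with an estimated correlation, and by fry, where the residual degrees of freedom allow. For single libraries a list's median is ranked among 10000 random lists of similar expression. Members of a random list are drawn independently, so the percentile ignores that genes of a real list move together. Cd8a, Gzma, Trbc2, Trac, Ms4a1, Cxcr2, Loxl2, Hba-a1 and Hba-a2 are not analysed here.

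Named genes are the 12 highest and 12 lowest called genes with 1 sign in every state for the side, the 8 and 8 for naive, and the 6 and 6 with 1 sign in both pairs for time, LEV and side difference. For withdrawal they are the 5 highest and 5 lowest ratios at a mean CPM of at least 10. Up to 4 members of a list with the smallest p and a panel of 17 glial, synaptic and inflammatory genes were added. Some of these list and panel genes are not reported here by name, though list results count them. Genes that share tags with a named gene, those that set libraries apart, such as Atp5e, and those of the closing section that fall outside this rule were chosen after their values were seen.

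The tests were checked on simulated data drawn from negative binomial counts at each gene's level and spread, with changes of 1.5, 2, 4 and 8-fold given to a small share of genes. The spread was estimated with state and side in the model, so it leaves out differences between states. The false share of these simulated, or spike-in, calls also depends on how many genes were changed. It is therefore not an estimate for the real calls. Alternatives were a prior count of 0.25, no expression limit, a mean CPM of at least 5, median centring per library, TMM factors, quasi-likelihood tests in edgeR 4.0.16 on the recovered tags, models without the second factor, and leaving out each library or state. Counting sets of genes with shared tags once, asking for 2-fold, and exchanging sides within states were chosen after seeing the data. Values were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9.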

Results

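Photothrombosis makes a small cortical stroke: rose bengal, a light-sensitive dye, is injected and a lamp over the left parietal cortex then clots the vessels below it. The series asks how the cortex changes after such a stroke and whether levetiracetam, an anti-seizure drug that binds the synaptic vesicle protein SV2A, alters those changes. The libraries are CAGE (cap analysis of gene expression), in which short tags are counted at the 5′ ends of transcripts. There are 11 libraries of whole cortex from male C57BL/6N mice, 1 per group. One comes from naive mice, and the other 10 are the infarcted and the non-infarcted side at 7 d, 7 d with levetiracetam, 1 m, 1 m with levetiracetam, and 2 m after 2 weeks of withdrawal. Library totals run from 12928291 to 21000367 tags, and 92.3% to 97.3% of them lie in the 22377 genes of the table. No group has a second library, so the side test treats the 5 states as repeats of the same contrast, and the tests of time and drug have 1 residual degree of freedom. Beside that 1, their moderated t takes its spread from other genes. This counts as 45.3 prior degrees of freedom on the infarcted side, 13.9 on the other and 64.4 for the side difference. A small p in these tests therefore does not show that both pairs of a gene agree. The labels do not state whether both sides come from the same mouse or pool, nor how many mice stand behind a library, so p-values describe these libraries and not a population of mice.

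The infarcted side carries a lasting microglial, astrocyte and lysosomal programme in all 5 states. Lgals3, which encodes galectin-3 of phagocytic microglia and macrophages, was 183.4, 133.2, 87.2, 18.2 and 89.8 CPM on the infarcted side at 7 d, 7 d with levetiracetam, 1 m, 1 m with levetiracetam and 2 m, against 1.44 to 4.67 CPM on the other side. Gfap, the intermediate filament of reactive astrocytes, rose by a log2 difference of 1.73 (standard error 0.11; adjusted p = 0.000784), from 384.4 to 615.3 CPM against 107.3 to 198.8 CPM. Sv2a, the levetiracetam target, was not called at −0.12 (adjusted p = 0.496).

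**Figure D1:**
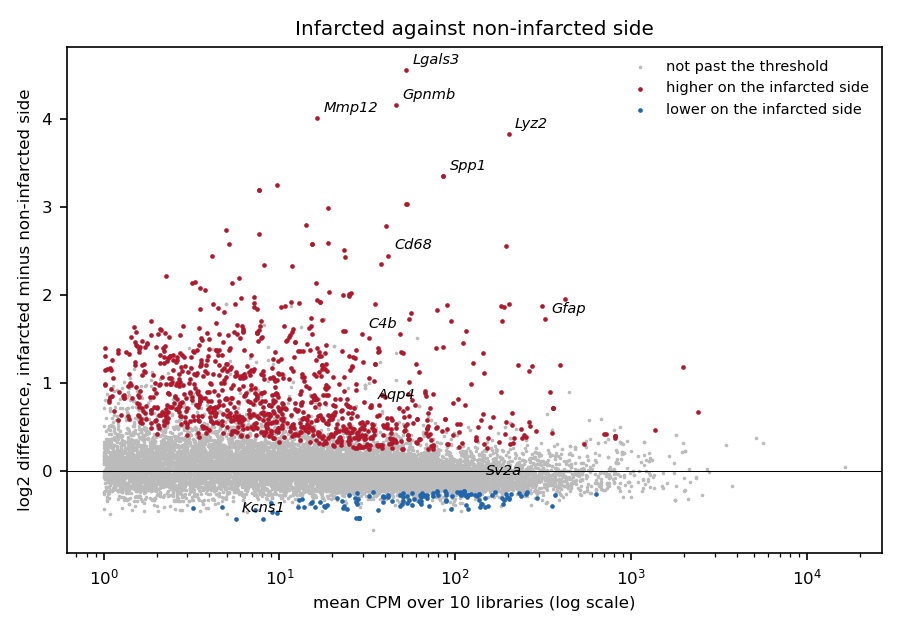
Difference between the infarcted and non-infarcted side for every tested gene against its mean expression, with called genes coloured.

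Of 16229 genes tested, 1136 were called, 1008 higher and 128 lower on the infarcted side, and 1127 of them have the same sign in all 5 states. A difference of at least 2-fold was reached by 338, all of them higher. Besides Lgals3 at 4.55 (adjusted p = 0.00363), the largest rises were in Gpnmb, a lysosomal glycoprotein of lipid-laden phagocytes, at 4.15 (adjusted p = 0.005), Mmp12, the macrophage elastase, at 4.002 (adjusted p = 0.0102), Lyz2, the lysozyme of myeloid cells, at 3.83 (adjusted p = 0.00879), and Spp1, which encodes osteopontin, at 3.35 (adjusted p = 0.0247). Clec7a (3.24), Apoc4 (3.19), Col3a1 (3.04), Ms4a7 (2.98), Apobec1 (2.79), Wfdc17 (2.78) and Mmp3 (2.74) follow. Spp1 shares its tags with Gm42793, Apoc4 with Gm44805 and Col3a1 with Gm47302, so each pair is one signal. The lowest called genes are small in comparison: Tnnc1, slow troponin C, at −0.55, the potassium channel modifier Kcns1 at −0.54, a T cell receptor beta joining segment group from Trbj2-1 to Trbj2-7 with Trbd2 at −0.53, Rnf39 at −0.47 and Serpinb8 at −0.46. On the panel, the lysosomal marker Cd68 rose by 2.44 (adjusted p = 0.00924), the microglial Aif1 by 1.13 (adjusted p = 0.028) and the astrocyte water channel Aqp4 by 0.75 (adjusted p = 0.005).

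Most members of the microglial, complement, lysosome and antigen presentation lists were called. In the disease-associated microglia list 14 of 16 members rose (16 when adjusted over the list alone), among them Lpl at 1.37 and Cd9 at 1.35. The homeostatic microglia list, whose genes mark resting microglia, rose as well, with 8 of 12 called (10 over the list alone), including Cx3cr1 at 0.93, Csf1r at 0.88 and P2ry12 at 0.47. In the macrophage and monocyte list 4 of 9 rose (7 over the list alone), Cd36 by 2.19 and Mrc1 by 0.58. Complement rose in 12 of 13 genes (13 over the list alone), with C1qc and Itgb2 both at 1.87 and C4b at 1.56. Lysosome and lipid handling rose in 13 of 14 (14 over the list alone), Abca1 by 1.80 and Ctss by 1.71. Antigen presentation rose in 11 of 12 (12 over the list alone), B2m by 1.45 and H2-K1 by 1.40. Cytokines and chemokines rose in 9 of 11 (10 over the list alone), with Ccl6 at 1.92, Cxcl16 at 1.84 and Cxcl10 at 1.56. Interferon response rose in 8 of 14 (13 over the list alone), Irf7 by 1.27 and Ifitm3 by 1.21. Reactive astrocyte genes rose in 11 of 14 (11 over the list alone), with Vim at 1.73, Serpina3n at 1.65 and Cd44 at 1.58, while homeostatic astrocyte genes rose in 2 of 12 (5 over the list alone), Aqp4 and the gap junction gene Gja1 at 0.54.

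Scar, vessel and myelin lists differ in the share of genes called. The fibrillar and basement membrane matrix list rose in 7 of 13 (13 over the list alone), Lox by 1.96 and Sparc by 0.91. The meningeal fibroblast list rose in 3 of 10 (7 over the list alone), Lum by 1.98 and Dcn by 1.35. Pericyte and smooth muscle genes rose in 4 of 10 (5 over the list alone), Anpep by 1.39 and Rgs5 by 0.51, and endothelial genes in 1 of 12 (4 over the list alone), the efflux pump Abcb1a by 0.66. Myelin and oligodendrocyte genes rose in 11 of 14 (14 over the list alone) with a median of 0.37, for example Cldn11 at 0.75 and Mog at 0.41, and oligodendrocyte precursor genes in 3 of 10 (6 over the list alone), Enpp6 by 0.62 and Bcas1 by 0.48. Heat shock and stress genes rose in 2 of 11 (2 over the list alone), Hmox1 at 1.48 and Atf3 at 1.40. Glucocorticoid response genes rose in 2 of 10 (3 higher and 1 lower over the list alone), the metallothioneins Mt2 at 0.90 and Mt1 at 0.43. Perineuronal matrix genes rose in 1 of 7 (2 over the list alone), Vcan by 0.65, and cell cycle genes in 0 of 12 (4 over the list alone). Neutrophil genes rose in 1 of 6 (1 over the list alone), Csf3r at 0.85, and the T cell (3 tested) and B cell and plasma cell (2 tested) lists held 0 called genes.

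Few members of the neuronal and synaptic lists were called between the sides. Voltage-gated channels fell in 2 of 18 (7 over the list alone), Kcnc1, which lets fast-spiking interneurons fire, by a log2 of −0.27 and Scn8a by −0.26. Immediate early genes, which follow neuronal firing, fell in 3 of 18 (7 lower and 1 higher over the list alone): Nr4a1 at −0.43, Egr4 at −0.34 and Dusp1 at −0.34, with Fos at −0.22 (adjusted p = 0.255). Cholesterol synthesis genes fell in 5 of 15 (8 over the list alone), Sqle at −0.38 and Insig1 at −0.37. GABA-A receptor subunits held 0 called of 12 (0 over the list alone) with a median of −0.17, inhibitory neuron genes 0 of 12 (5 lower over the list alone), excitatory neuron genes 0 of 11 (0), ionotropic glutamate receptors 0 of 15 (0), synaptic vesicle genes 0 of 16 (0) and cation-chloride transport 0 of 9 (2 higher). Also not called were Gabra4 at −0.20, Gabrd at −0.20, the chloride transporters Slc12a2 at 0.19 and Slc12a5 at −0.13, the glutamate transporter Slc1a2 at −0.02, the potassium channel Kcnj10 at 0.26 and Bdnf at −0.19. Circadian clock genes (0 of 12), blood (0 of 2), choroid plexus (0 of 4) and hippocampus (0 of 6) held none, thalamus 2 of 8 (3 over the list alone), Prkcd at 1.10 and Tcf7l2 at 0.82, and striatum 0 of 9 with a median of 0.38, which is outside cortex. Il1b and Tnf, inflammatory cytokines of the panel, lay below the expression limit.

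Gene-list ranks by camera passed in 27 lists with the preset correlation of 0.01, and in 0 with an estimated correlation. The disease-associated microglia, complement, antigen presentation, lysosome, homeostatic microglia, interferon, cytokine, reactive astrocyte, meningeal, pericyte, myelin and precursor lists all stand at adjusted p = 0.329 with an estimated correlation. The matrix, homeostatic astrocyte, voltage-gated channel, immediate early, GABA-A and inhibitory lists stand at adjusted p = 0.393 with an estimated correlation. Rotation tests by fry passed in 9 lists, the reactive astrocyte list at adjusted p = 0.014 and the disease-associated microglia list at adjusted p = 0.0264. edgeR called 1281 genes between the sides.

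A share of 88.7% of the called genes is higher on the infarcted side. With values centred on the median gene 1271 were called and 69.1% were higher, and with TMM factors 1069 and 74.8%. Without the state factor 245 were called, and with mean CPM of at least 5 required, 732. Leaving out 7 d left 103 called genes, leaving out 7 d with levetiracetam 161 and leaving out 1 m 71, against 1174 without 1 m with levetiracetam and 1288 without 2 m. Spiked changes were recovered in 64%, 94%, 100% and 100% of genes at 1.5, 2, 4 and 8-fold, with 9.23% of calls false.

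The macrophage, matrix and disease-associated microglia lists had smaller side differences at 1 m and 2 m than at 7 d. At 7 d, 7 d with levetiracetam, 1 m, 1 m with levetiracetam and 2 m the median side difference of the macrophage and monocyte list was 2.69, 2.28, 0.64, 0.10 and 0.78, and that of the matrix list 2.37, 2.77, 0.63, 0.24 and 0.42. Reactive astrocyte genes were at 0.90, 1.01, 1.07, 0.75 and 0.66, and antigen presentation at 1.49, 1.83, 1.55, 0.66 and 0.96. The disease-associated microglia list went from 2.97 and 2.90 to 1.34, 0.88 and 1.28. GABA-A receptor subunits were at −0.33, −0.25, −0.06, −0.11 and 0.07.

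**Figure D2:**
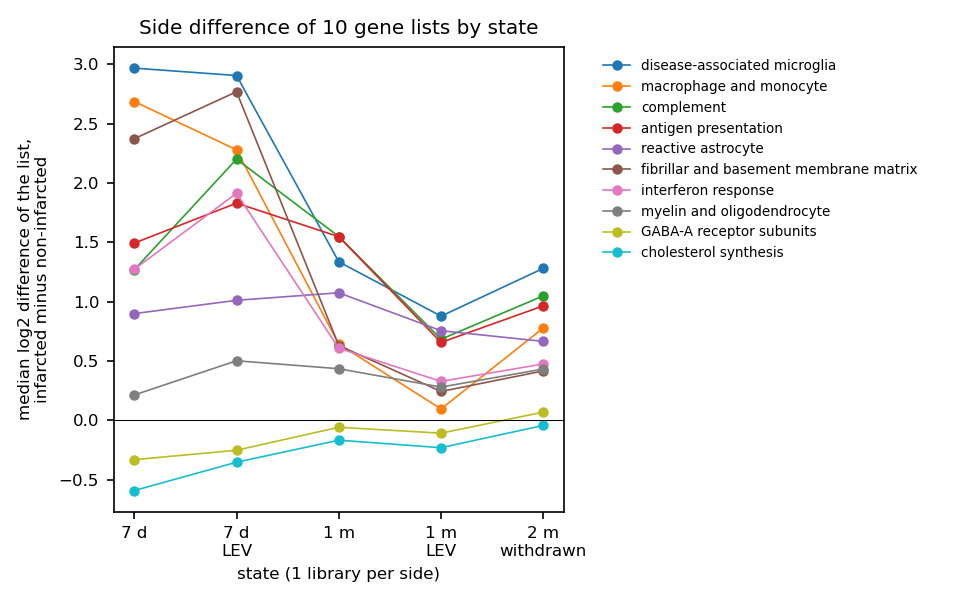
Median side difference of fixed gene lists in each of the 5 states.

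Against naive cortex the infarcted side lies above in glial genes such as Gfap, but 1 gene passed the test, and it fell. Ttr, transthyretin, which in brain comes mostly from choroid plexus, fell by a log2 of −4.40 (adjusted p = 0.018). It stands at 349.7 CPM in the naive library, 195.3 CPM in the non-infarcted 1 m levetiracetam library and 9.79 to 24.7 CPM in the others, so the call rests on the naive library. Gfap at 2.16 (standard error 0.27; adjusted p = 0.189), the complement gene C4b at 1.504 (adjusted p = 0.343) and Lgals3 at 5.15 (adjusted p = 0.81) were not called. Serpina3n (1.70), Clec7a (3.96), Vim (2.06) and Cd68 (2.60) were not called either. Sv2a at −0.05 and Slc12a5 at −0.25 were near the naive value.

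With 1 naive library, assumed to vary like the rest, the test called 1 of 16367 genes in limma and 1 in edgeR, with 624 at unadjusted p < 0.05. Leaving out 1 m or 2 m left 0, and leaving out 1 m with levetiracetam left 2. Adjusted over the list alone, antigen presentation passed in 12 of 12 genes (H2-Q7 at 1.25 and Psmb8 at 1.83), reactive astrocyte in 7 of 14, disease-associated microglia in 7 of 16, cytokines in 5 of 12, complement and macrophage in 2 each and choroid plexus in 2 lower, against 0 over all genes in each but choroid plexus with 1. In camera 25 lists passed with the preset correlation and 0 with an estimated correlation, where antigen presentation stands at adjusted p = 0.259 and choroid plexus at adjusted p = 0.182. The spike-in test recovered 59.2% of 2-fold and 97.9% of 4-fold changes. Its spread leaves out differences between states, which the real test holds, so these shares can be too high. Genes with larger differences, such as Lgals3, were not called.

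The non-infarcted side was set against the 1 naive library and no gene was called, which does not show that they are alike. Fos, an immediate early gene switched on by neuronal firing, was 7.43 CPM in naive and 20.7 and 20.9 CPM at 7 d and 7 d with levetiracetam, a mean log2 of 0.93 over the 5 states, and was not called. Egr2 at 1.09, Egr1 at 0.60 and Npas4 at 0.49, further firing-dependent genes, were not called. Fkbp5 at −0.74 and Hif3a at −0.91, both driven by glucocorticoid hormone, were not called. Gfap at 0.43, Lgals3 at 0.60 and Lyz2 at 0.66 were far below their levels on the infarcted side.

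Limma called 0 of 15983 genes, with 151 at unadjusted p < 0.05 and a smallest adjusted p of 0.466, and edgeR called 0. Without an expression limit 1 was called, and 1 each without 1 m and without 1 m with levetiracetam. Immediate early genes were positive in 16 of 18 with a median of 0.38 (adjusted p = 0.579 with an estimated correlation), and glucocorticoid response genes in 0 of 10 with a median of −0.54 (adjusted p = 0.369 with an estimated correlation). The interferon response list has a median of 0.31 (adjusted p = 0.579 with an estimated correlation), with Ifitm3 at 0.48 and Ifit1 at 0.69. In camera 10 lists passed with the preset correlation and 0 with an estimated correlation. Of spiked changes 62.5% were recovered at 2-fold and 98% at 4-fold. The simulated spread leaves out differences between states, which the real test holds, so these shares can be too high.

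Between 7 d and 1 m genes of scar tissue and proliferation fell on the infarcted side. Col3a1, a fibrillar collagen of scar tissue, fell by a log2 of −4.28 (adjusted p = 9.68e-18), from 221.8 and 238.9 CPM at 7 d to 31.1 and 3.38 CPM at 1 m. Spp1 fell by −4.05, from 303.2 and 456.3 CPM to 26.0 and 17.7 CPM. H19, an imprinted RNA of growing tissue that shares its tags with Mir675, fell by −4.41, and Plin2, which coats lipid droplets, by −3.96. Gfap fell by only −0.50 (adjusted p = 0.0137), and Lcn2, a lipocalin of reactive astrocytes and neutrophils, rose by 1.13.

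The time test called 2732 of 16399 genes, 864 higher and 1868 lower at 1 m, 611 by at least 2-fold (55 higher, 556 lower). All 13 matrix genes fell (13 over the list alone), Col1a1 by −3.77 and Bgn by −2.51. Disease-associated microglia fell in 14 of 16 (15 over the list alone), Ctsd by −2.55, macrophages in 8 of 9 (9), Arg1 by −2.64, interferon response in 13 of 15 (13), Isg15 by −2.22, and lysosome and lipid handling in 12 of 14 (12). Cell cycle fell in 10 of 14 (12 over the list alone), with the mitotic genes Top2a at −2.58 and Birc5 at −2.46, homeostatic microglia in 9 of 12 (10), cytokines in 9 of 12 (9) and complement in 8 of 14 (8). Reactive astrocyte genes fell in 5 and rose in 1 of 14 (7 and 1 over the list alone), Timp1 by −1.53 and Vim by −0.96, and antigen presentation fell in 4 and rose in 1 of 12 (4 and 1). Cd68 fell by −1.93, Aif1 by −1.47, Kcnj10 by −0.60 and Aqp4 by −0.50.

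Some neuronal genes rose over the same interval, but not on this side only. The called genes that rose showed a median of 1.08 of their change on the non-infarcted side, where Vip and Slc17a7 rose too. Vip, a peptide of disinhibitory interneurons, rose by 0.86 (adjusted p = 0.000218), and with Gad1 at 0.48 and Gad2 at 0.44, the GABA-making enzymes, and Reln at 0.53, 5 of 12 inhibitory neuron genes were called (7 over the list alone). Excitatory neuron genes rose in 2 of 11 (2 over the list alone), ionotropic glutamate receptors in 2 of 15 (2), and synaptic vesicle genes in 1 of 16 with 1 lower (1 and 1). Gabra5, a GABA-A receptor subunit, rose by 0.54 (adjusted p = 0.00547). Voltage-gated channels rose in 5 of 18 (6 over the list alone), Kcnt1 by 0.52 (adjusted p = 0.00853). The vesicular glutamate transporter Slc17a7 rose by 0.92, mostly through the 1 m levetiracetam library. It was 481 CPM at 7 d, 543 CPM at 7 d with levetiracetam, 615 CPM at 1 m and 1516 CPM at 1 m with levetiracetam. Stxbp3, which sets the naive and 1 m libraries apart from those of 7 d and 2 m, rose as well. Striatum genes rose in 8 of 9 (8 over the list alone), Drd2 by 0.88.

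**Figure D3:**
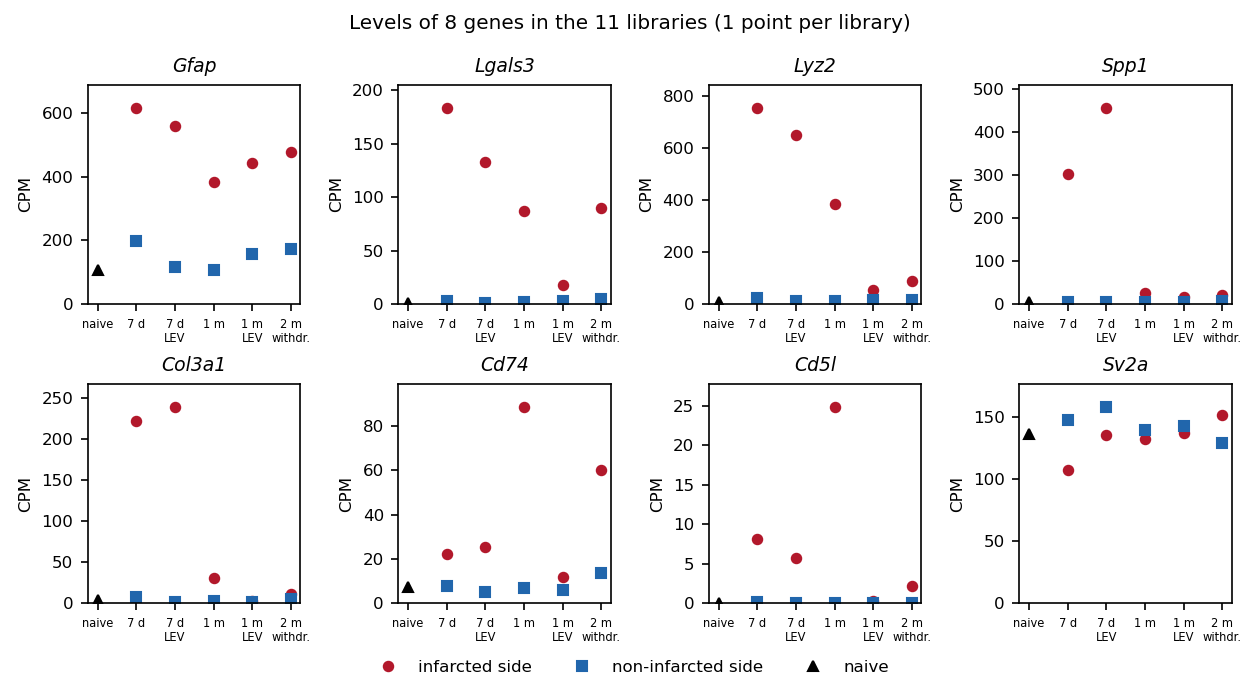
CPM of lesion genes and of Sv2a in each of the 11 libraries.

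The highest rises are of another kind: Rny1, a small cytoplasmic RNA, at 2.13, Stxbp3 at 1.81, Gm37376 at 1.90, Gm22513 at 1.77, Rpl9-ps6 at 1.68 and Cox5b-ps at 1.65. The false share is 32.4% of spike-in calls, and 18.8% among spike-in calls of at least 2-fold. With few genes changed in the simulation, this is not the false share of the 2732 calls. edgeR called 2380 genes, and without the drug factor 1547 were called. Of the 2732 calls 31.6% are higher, and 46.5% of 2648 with values centred on the median gene. With the drug factor dropped as well, leaving out 7 d left 704 genes and leaving out 7 d with levetiracetam 806, against 4962 without 1 m and 2260 without 1 m with levetiracetam.

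On the non-infarcted side the genes that fell from 7 d to 1 m include some of neutrophils, neuronal firing and glucocorticoid response. S100a8, a calcium-binding protein of neutrophils, fell by −1.96 (adjusted p = 0.000506), and Camp, a neutrophil granule peptide, by −2.34 (adjusted p = 0.000845). Fos fell by −0.76 (adjusted p = 0.006) and Junb by −0.95 (adjusted p = 0.000726). Slc12a2, the sodium-potassium-chloride importer that makes GABA depolarising, rose by 0.59 (adjusted p = 0.0231), and its counterpart Slc12a5 was unchanged in the test at −0.01 (adjusted p = 0.979).

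Of 15931 genes 1979 were called, 952 higher and 1027 lower, 236 by at least 2-fold (190 higher, 46 lower). Neutrophil genes fell in 5 of 6 (5 over the list alone), S100a9 by −2.04 and Ngp by −1.98 besides Camp. Immediate early genes fell in 8 of 18 (10 over the list alone), Egr4 by −0.66 and Egr2 by −0.69, and glucocorticoid response in 5 of 10 (5), Sgk1 and Tsc22d3 both by −0.96. Synaptic vesicle genes fell in 4 and rose in 1 of 16 (6 and 1 over the list alone), Stx1a by −0.94 and Cplx2 by −0.74. Homeostatic astrocyte genes fell in 4 of 12 (4), Gja1 by −0.73 and Kcnj10 by −0.66, precursor genes in 4 with 1 higher of 10 (5 and 2), Olig2 by −0.89, and circadian genes in 3 of 12 (3 lower and 2 higher over the list alone), Per1 by −0.61. Vip rose by 0.98 and Slc17a7 by 0.81. Rpl9-ps6 (2.19), Ttr (2.18), Gm10800 (2.06), Gm22513 (2.03), Rpl21-ps15 (1.89) and Stxbp3 (1.86) rose most, Ttr through the 1 m levetiracetam library alone, and Gm15580 (−2.35) and Mir1982 (−1.98) are among the largest falls.

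S100a8 stands at 58.8 CPM in the 7 d non-infarcted library, 29.8 CPM in its infarcted partner and at most 12.998 CPM elsewhere, so 1 library enlarges the neutrophil result. The levetiracetam pair, without that library, fell less: S100a8 from 6.96 CPM at 7 d to 2.71 CPM at 1 m, and Camp from 2.82 to 0.667 CPM. The false share is 25.7% of spike-in calls, and 4.13% among calls of at least 2-fold. edgeR called 2038. The share of calls that is higher is 48.1%, against 61.1% with median centring and 70.9% of 1373 with TMM factors. With the drug factor dropped as well, leaving out 7 d left 702, 7 d with levetiracetam 1234, 1 m 2907 and 1 m with levetiracetam 2199.

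With levetiracetam the infarcted side held less of some macrophage genes, and most of that difference lies at 1 m. Cd5l, a macrophage survival protein, fell by −2.37 (adjusted p = 8.24e-05), being 24.8 CPM at 1 m and 0.312 CPM at 1 m with levetiracetam, against 8.14 and 5.74 CPM at 7 d. Lyz2 fell by −1.50 (adjusted p = 0.000161), with 383.5 against 54.4 CPM at 1 m and 754.6 against 650.3 CPM at 7 d. Lgals3 fell by −1.33 (adjusted p = 4.12e-05), with 87.2 against 18.2 CPM at 1 m. Gfap was not called at 0.03 (adjusted p = 0.983). It was 615.3 CPM untreated and 557.6 CPM with levetiracetam at 7 d, and 384.4 CPM untreated and 444.2 CPM with levetiracetam at 1 m. The drug target Sv2a was not called at 0.19 (adjusted p = 0.79).

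The test called 85 of 16399 genes, 21 higher and 64 lower with levetiracetam, 33 by at least 2-fold (3 higher, 30 lower), and 1370 had unadjusted p < 0.05. Wfdc17 fell by −1.92, Mmp12 by −1.90 (adjusted p = 2.82e-07), the chemokine Ccl8 by −1.67 and the acute-phase Saa3 by −1.51. Disease-associated microglia fell in 4 of 16 (4 over the list alone), Clec7a by −0.83, Tyrobp by −0.64 and Gpnmb by −0.89, though Gpnmb is lower at 1 m only. Macrophage genes fell in 2 of 9 (3 over the list alone), Ms4a7 by −1.15 besides Lyz2. Antigen presentation fell in 3 of 12 (6 over the list alone), the class II genes H2-Eb1 by −1.26 at both times and Cd74 by −1.29 and H2-Ab1 by −1.28 at 1 m only. Cytokines fell in 2 of 12 (3), Ccl6 by −1.18 and Cxcl16 by −0.79, matrix in 2 of 13 (3), Col3a1 by −1.38 and Col1a1 by −1.25 at 1 m only, and neutrophil genes in 2 of 5 (4), Camp by −1.51 and S100a8 by −1.03. Acta2, smooth muscle actin, fell by −0.80, Plin2 by −0.74 and the haemoglobin gene Hbb-bs by −0.97. At 7 d with levetiracetam S100a8 was 10.0 CPM against 29.8 CPM without, and Hbb-bs 17.6 against 62.0 CPM. Whether less blood in that library lowered the neutrophil genes was not tested. Higher were Ybx2 at 1.09, Drd2 at 0.99, Lrrc10b at 0.92, Mt2 at 0.83, Slc25a23 at 0.81 and Slc17a7 at 0.74. GABA-A receptor subunits held 0 of 12 (1 higher over the list alone). Striatum genes rose in 1 of 9 (8 over the list alone), Drd2.

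The drug result depends on the model and on scaling. The fit without the time factor called 0 genes, and so did every set with 1 library left out, which also lacks that factor and so does not test single libraries. Without the 1 m levetiracetam library and the time factor Lyz2 stood at 0.27, Lgals3 at 0.07, Mmp12 at 0.14, Gpnmb at 0.99 and Col3a1 at 1.504, the opposite direction, because 7 d with the drug is then set against the mean of 7 d and 1 m. Median centring called 12 genes, of which 8.33% are higher against 24.7% in the main test, and TMM factors called 0. A prior count of 0.25 gave 28, no expression limit 11, a limit of CPM 5 gave 209 with 39.7% higher, and edgeR called 17. Of spike-in calls 37.0% were false, and 13.1% among those of at least 2-fold.

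On the non-infarcted side levetiracetam was linked to 1 gene. S100a8 fell by −2.05 (adjusted p = 0.0359), more at 7 d, where it was 58.8 CPM untreated and 6.96 CPM with levetiracetam. At 1 m it was 7.48 CPM untreated and 2.71 CPM with levetiracetam. The untreated 7 d library has the highest S100a8 of all libraries. Hbb-bs fell with levetiracetam at 7 d too, from 84.8 to 25.2 CPM, and was 82.7 and 79.7 CPM at 1 m. Whether less blood in the 7 d levetiracetam library lowered S100a8 was not tested. Camp at −2.23 was not called (adjusted p = 0.106), and 5 of 6 neutrophil genes were lower over the list alone against 1 over all genes. Sv2a at 0.06 and the chloride exporter Slc12a5 at 0.46 (adjusted p = 0.963) were not called. Striatum genes were lower in 5 of 9 over the list alone and in 0 over all genes. Limma called 1 of 15931 genes with 798 at unadjusted p < 0.05, and edgeR called 9. Of spike-in calls 31.1% were false. With the time factor dropped as well, leaving out 7 d left 23 and leaving out 1 m 24, against 1 each without either levetiracetam library. A prior count of 0.25 gave 3 and median centring 2, and TMM factors, no expression limit, a limit of CPM 5 and no time factor each gave 0.

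The side difference itself shrank from 7 d to 1 m. Spp1 fell by −3.95, Col3a1 by −3.75, H19 by −4.16 and Eln, elastin, by −3.89, while Lcn2 rose by 2.41, having risen on the infarcted side and fallen on the other. The neutrophil genes S100a9 (1.62), Ngp (1.32), Camp (1.30) and S100a8 (1.27) rose because they fell more on the non-infarcted side, and Chil1, a chitinase-like protein, rose by 1.30. Of 16228 genes 888 were called, 39 higher and 849 lower, 401 by at least 2-fold (9 higher, 392 lower). Matrix fell in 13 of 13 (13 over the list alone), disease-associated microglia in 13 of 15 (15), lysosome in 11 of 14 (12), interferon in 10 of 14 (12), macrophage in 7 of 9 (7), complement in 7 of 13 (7), cell cycle in 7 of 12 (9) and cytokines in 7 of 12 (8). Striatum rose in 4 of 9 (6 over the list alone), synaptic vesicle genes in 2 of 16 (9), and GABA-A subunits in 0 of 12 (0). Of spike-in calls 31.3% were false. edgeR called 594, median centring left 271, TMM factors 431 and the fit without the drug factor 503. With the drug factor dropped as well, leaving out 7 d left 162 and leaving out 7 d with levetiracetam 265, against 857 without 1 m and 750 without 1 m with levetiracetam.

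With levetiracetam the side difference changed in 28 genes, 16 higher and 12 lower. Cd5l fell by −2.39, Wfdc17 by −1.96, Mmp12 by −1.85, Saa3 by −1.62 and Lyz2 by −1.41, the macrophage genes of the infarcted side. Ms4a7 fell by −1.20, and Ttr by −1.33, which rests on the 195.3 CPM of the non-infarcted 1 m levetiracetam library. Striatum genes rose in 8 of 9 (9 over the list alone), the dopamine receptor Drd2 by 1.17, the adenosine receptor Adora2a by 0.98 and the opioid peptide Penk by 0.86. The median side difference of this list was −0.43 at 7 d, 0.56 at 7 d with levetiracetam, 0.24 at 1 m and 0.77 at 1 m with levetiracetam. Uneven amounts of tissue from outside the cortex and a drug effect cannot be told apart here. Neutrophil genes rose in 3 of 6 (5 over the list alone), Ngp by 1.35, S100a8 by 1.02 and S100a9 by 0.99. These rises were larger in the 7 d pair, which holds the untreated 7 d non-infarcted library (S100a8 at 58.8 CPM), than in the 1 m pair. Unadjusted p < 0.05 was reached by 539 genes, and edgeR called 7. Of spike-in calls 20% were false. Median centring, TMM factors and no time factor each called 0, a prior count of 0.25 gave 7, no expression limit 2 and a limit of CPM 5 gave 41. With the time factor dropped as well, leaving out 7 d or 1 m left 0, leaving out 7 d with levetiracetam 144 and leaving out 1 m with levetiracetam 25.

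At 2 m after withdrawal several inflammatory genes were above the 1 m levetiracetam library on the infarcted side. Mmp12 was 41.8 against 1.09 CPM, a ratio of 38.2 (95% interval 24.8 to 62.1), Cd74 60.2 against 11.9 CPM, a ratio of 5.07 (4.39 to 5.88), and Lgals3 89.8 against 18.2 CPM, a ratio of 4.93 (4.39 to 5.55). Against the untreated 1 m library the ratios are 3.25 for Mmp12, 0.681 for Cd74 and 1.03 for Lgals3. Lyz2 was at 1.61 against 1 m with levetiracetam and at 0.229 against untreated 1 m, and Wfdc17 (7.64 against 13.2 CPM) and Apoc4 (1.08 against 12.6 CPM) were below the 1 m levetiracetam library. H2-Eb1 stood at a ratio of 5.60 (4.01 to 8.00) and Scd1, a fatty acid desaturase, at 4.29 (3.72 to 4.95). Gfap was at 1.07 (1.04 to 1.11) and Sv2a at 1.11. These intervals cover counting error only, since each value is 1 library and time and withdrawal change together. The 2 m libraries also lie apart from all 1 m libraries in genes such as Atp5e, here 219 against 882 CPM at 1 m with levetiracetam. Each ratio of 2 m to 1 m, on either side, crosses that division of libraries.

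On that side 203 of 11001 genes differed by at least 2-fold, 118 higher and 85 lower, against 160 (36 higher, 124 lower) when compared with untreated 1 m. The median of all genes lies at 0.11, and relative to it 64 are higher and 159 lower. The lowest were Rpl22-ps1 at 0.112, Rpl9-ps6 at 0.130, Rpl21-ps15 at 0.149, Lcn2 at 0.167 (0.127 to 0.217) and Apoc1 at 0.182. Of these, Rpl9-ps6 is also lower in all 7 d and 2 m libraries than in all naive and 1 m libraries. The matrix list has a median log2 of 0.61, percentile 99.99 of 10000 random lists, cell cycle 0.68 (100), homeostatic astrocyte 0.46 (99.87), macrophage 0.55 (99.59), precursor 0.46 (98.99), cholesterol synthesis 0.37 (98.65) and cation-chloride transport −0.24 (1.38). These percentiles, and those of the other side, set the 2 m library against the 1 m levetiracetam library alone and ignore correlation within a list. In the side test that correlation was estimated at 0.95 for matrix and 0.76 for cell cycle genes. The reference can matter: Col1a2 of the matrix list was 15.5 CPM at 2 m, 5.73 CPM at 1 m with levetiracetam and 20.9 CPM at untreated 1 m. Sparc of that list was 98.9, 43.0 and 45.6 CPM, above both.

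On the non-infarcted side Selenop, which carries selenium to the brain, was 552 against 125 CPM, a ratio of 4.43 (4.24 to 4.63), and Spop, Id4, Srsf3 and Clip3 had ratios of 3.999, 3.88, 3.73 and 3.45. Against untreated 1 m the ratios are 3.14 for Selenop, 3.22 for Spop, 2.34 for Id4, 2.43 for Srsf3 and 3.81 for Clip3, and Spop, Id4, Srsf3 and Clip3 are also lower in all naive, 1 m and 1 m levetiracetam libraries than in all those of 7 d and 2 m, Clip3 at 28.8 to 35.4 against 74.9 to 124.4 CPM. Ttr was lower at 0.0786, with Rpl21-ps15 at 0.0728, Gm6063 at 0.0871, Rpl22-ps1 at 0.0999 and Mt2 at 0.114. Against untreated 1 m the ratios are 0.777 for Ttr, 0.283 for Rpl21-ps15, 0.107 for Gm6063, 0.204 for Rpl22-ps1 and 0.342 for Mt2. The chloride importer Slc12a2 was at 0.390 (0.338 to 0.448), Sv2a at 0.906 and Gfap at 1.10. Of 10730 genes 368 differed by at least 2-fold, 110 higher and 258 lower, against 305 (69 higher, 236 lower) when compared with untreated 1 m. Matrix genes have a median of 0.47 (percentile 99.87), cell cycle 0.63 (100) and homeostatic astrocyte 0.31 (98.31), while voltage-gated channels are at −0.28 (0.99) and inhibitory neuron genes at −0.30 (1.86).

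Some genes separate libraries irrespective of side. Atp5e, a subunit of mitochondrial ATP synthase, is 584 to 925 CPM in the naive, 1 m and 1 m levetiracetam libraries and 219 to 345 CPM in the others. Rpl9-ps6 is 18.2 to 33.0 against 4.27 to 7.90 CPM and Stxbp3 17.9 to 22.3 against 2.82 to 6.73 CPM over the same split, and Rny1 is 20.5, 24.5 and 23.6 CPM in naive and both 1 m libraries and at most 1.37 CPM elsewhere. Slc17a7 is 1516 and 1738 CPM in the 1 m levetiracetam libraries and 481 to 861 CPM in the rest. Hbb-bs, from blood, is 132 CPM in the naive library. Time and drug differences in such genes cannot be separated from how the libraries were made.

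**Figure D4:**
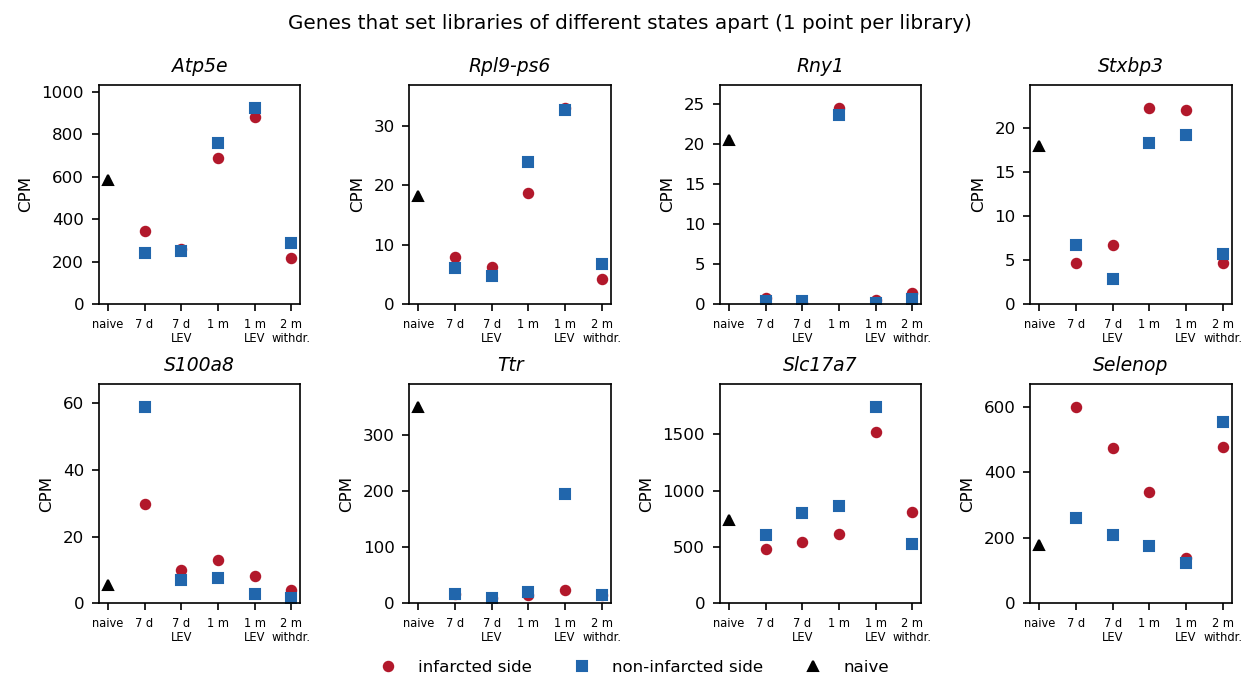
CPM of genes that set groups of libraries apart, in each of the 11 libraries.

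Chromosome positions follow GENCODE M21 on GRCm38. Gfap lies on chromosome 11 at 102887336 to 102900912 and Lgals3 on chromosome 14 at 47367751 to 47386160.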

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

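The tests in this part were chosen after the results they bear on were seen, except that of marrow genes, which was written before its values were known.

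The side difference changed between 7 d and 1 m in 888 genes and with levetiracetam in 28 genes, each by a test of the difference itself, as the report gives. Dixon's test for 1 outlier among the 5 states (critical value 0.71) passed in 0 of 36 list medians and can miss 2 states that lie apart together. The neutrophil list, at −1.47 in 7 d, came nearest at 0.675.

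The infarcted side differed from the other in 1136 genes. Of 100 divisions of the 10 libraries into 5 and 5, drawn from 126, 3 gave as many, the real one included, a share under 0.05, but most of these divisions leave some states unparted and so have fewer pairs to compare. The other 2 both gave 1466, more than the real one, and have the true sides in 7 d, 7 d with levetiracetam and 1 m and keep both libraries of each remaining state together, so with state in the model they are the same fit, a part of the real contrast. The 16 exchanges of sides within states keep the pairs and are too few for a share under 0.05: the real one gave 1136 and the highest other 0.

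The change from 7 d to 1 m on the non-infarcted side, in 1979 genes, is partly shared with a division of libraries: Atp5e, Stxbp3 and Rpl9-ps6 are high in naive, 1 m and 1 m with levetiracetam and low in 7 d, 7 d with levetiracetam and 2 m. If libraries were prepared in these sets, the 2 m library should lie at the 7 d end of the called genes, and if the tissue changed and stayed changed, at the 1 m end. With 7 d at 0 and 1 m at 1, its median position is 0.249 (quartiles −0.12 to 0.59; 30.9% of the genes nearer to 1 m), at the lower of the bounds of 0.25 and 0.75, and as the quartiles must lie past a bound, a rule set after the value was seen, the explanations cannot be told apart. The naive library lies at 0.666 (quartiles 0.469 to 0.848; 71.8% nearer to 1 m). Library sets would place it towards 1 m, and so would a return to the naive level by 1 m. On the infarcted side the position is 0.630 (quartiles 0.24 to 0.98), and they cannot be told apart for that change as a whole, whose rising genes show a median of 1.08 of their change on the other side too (quartiles 0.766 to 1.41). Both sides of a state fall in the same set, so a set should move both, but the non-infarcted side shows a median of 0.0981 (quartiles −0.02 to 0.24) of the fall in the 20 matrix and disease-associated microglia genes with a mean CPM of at least 5 there, which argues against library sets for these genes.

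Levetiracetam and lower macrophage genes on the infarcted side rest on the 1 m pair. More tissue from outside the cortex would dilute cortical neurons, and the excitatory neuron list has a median log2 ratio of 0.0533 between the 1 m libraries, but the striatum list lies at 0.181 (percentile 95.35 of random lists, with a bound of 95 set after it was seen), so such tissue and a drug effect cannot be told apart. Less lesion tissue would shrink all lesion genes alike: the reactive astrocyte list kept 1.03 of its excess (quartiles 0.435 to 1.30) and the disease-associated microglia list 0.590 (0.454 to 0.652), a ratio of 1.75 between the bounds of 1.5 and 2, so this cannot be told apart from a drug effect. A second pair, homeostatic microglia at 0.897 over macrophages at 0.125, gives a ratio of 7.18, but it was picked from a table of 10 lists after that table had been seen and decides nothing. Less of the lesion core, with the matrix list keeping 0.151, and a lowering at both times, with the disease-associated microglia list at −0.18 at 7 d, stay open too.

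S100a8 and Camp in the 7 d non-infarcted library stand apart, and residual blood in the 7 d non-infarcted library or marrow tissue in the 7 d non-infarcted library could bring them. Against blood, 1 library, naive, has more of the haemoglobin gene Hbb-bs (132 against 84.8 CPM) and less S100a8 (5.65 against 58.8 CPM), but naive mice had no stroke. In the 7 d non-infarcted library Hbb-bs and Hbb-bt (21.1 CPM) are higher than in the other 9 libraries after stroke (at most 82.7 and 15.0 CPM). Its Hbb-bs is close to the 82.7 CPM of the 1 m non-infarcted library, where S100a8 is 7.48 and Camp 2.54 CPM. With levetiracetam at 7 d, though, that side is low in both Hbb-bs (25.2 CPM) and S100a8 (6.96 CPM). With more than 1 library like naive asked for, a bound set after the value was seen, blood and neutrophils in the cortex cannot be told apart. Of the marrow precursor genes, 4 are in the table and 3, Elane, Ltf and Chil3, are highest in that library, fewer than the 4 that had been asked for. That bound was set for a longer list, and with 4 in the table each would have to be highest. Marrow and neutrophils in the cortex thus cannot be told apart. No biological explanation was tested for this pattern.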

How the results depend on the processing

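Counting shared tags once and asking for 2-fold were chosen after the results were seen. Calls at least 2-fold number 338 for the side, 611 and 236 for time on the infarcted and non-infarcted side, 33 for levetiracetam on the infarcted side, and 401 and 15 for the side difference over time and with the drug.

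With a limit of CPM 5 the side count is 732, and without state 245. Leaving out 1 state gave 71 to 1288 for the side, 0 to 2 for the infarcted side against naive and 0 to 1 for the other side. Without the second factor time on the infarcted side gave 1547. Leaving out 1 library together with the second factor gave 704 to 4962 for time on the infarcted side, 702 to 2907 on the non-infarcted side, 0 to 0 and 1 to 24 for levetiracetam, and 162 to 857 and 0 to 144 for the side difference over time and with the drug. A library alone in its group is then assumed to vary like the rest.

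Levetiracetam on the infarcted side (85 in the report) gave 28 with a prior count of 0.25, 11 with no expression limit, 209 at CPM 5, 12 with median centring, 0 with TMM factors, 17 in edgeR and 0 without time. On the non-infarcted side (1) the same settings gave 3, 0, 0, 2, 0, 9 and 0. The side difference over time (888) gave 271 with median centring, 431 with TMM factors and 503 without the drug. With the drug (28) it gave 7 with a prior count of 0.25, 2 with no expression limit, 0 with median centring, 0 with TMM factors, 7 in edgeR and 0 without time. The non-infarcted side against naive gave 1 with no expression limit. Except where the second factor or a library was left out, the cause was not tested.

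Lists that passed went from 27 to 0 with an estimated correlation and 9 by fry for the side, from 25 to 0 and 0 for the infarcted side against naive and from 10 to 0 and 0 for the other side. Taken singly, 115 list results lost their call and 111 kept their side of the threshold, most of them lists that had not passed before. Of the named genes' results, 1871 kept their side of the threshold, 645 lost their call, 6 gained one, 14 without a call moved and 20 turned direction.

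Those that turned did so where a library and the second factor were left out, so that time enters the drug contrast by construction. Their ranges over the 4 libraries left out are, for levetiracetam on the infarcted side, Tyrobp −1.54 to 0.27, Col3a1 −4.27 to 1.504, Plin2 −3.01 to 1.53, Lyz2 −3.28 to 0.273, Lgals3 −2.73 to 0.0735, Mmp12 −3.93 to 0.137, Clec7a −1.74 to 0.0706, Gpnmb −2.77 to 0.985, Ms4a7 −2.56 to 0.271, Cxcl16 −1.58 to 0.0025, Col1a1 −3.89 to 1.38 and Slc17a7 −0.00231 to 1.48. For the side difference with the drug they are S100a9 −0.00145 to 1.97, Mmp12 −3.87 to 0.175, Lyz2 −3.35 to 0.540, Ttr −2.76 to 0.0907 and Ms4a7 −2.55 to 0.149.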

Other observations

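The genes and tests below were chosen after the results were seen, except the age lists, which were written before their values were known.

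At 7 d the infarcted library with levetiracetam is higher than the one without in interferon response genes, with a median log2 ratio of 0.48 and 14 of 14 members higher (percentile 100 of random lists). In the matrix list 12 of 13 members are higher, with a median of 0.23. Both 2 m libraries hold Il1rl1, the receptor of interleukin-33, at 7.87 and 6.31 CPM, the imprinted Dlk1 at 16.4 and 14.4 CPM and the cell cycle inhibitor Cdkn2a at 4.503 and 5.16 CPM, infarcted and non-infarcted.

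Immunoglobulin segments stand out in the 2 m infarcted library: Ighv4-1 at 14.0, Igkv3-4 at 13.7 and Igkv4-57 at 13.4 CPM, and the joining chain Jchain at 10.5 CPM. Antibody-secreting cells in the 2 m infarcted library are a candidate source. Of 10 listed genes of such cells in the table, 5 are highest in that library (Jchain, Mzb1, Iglv1, Igkc and Iglc2), with more than 4 asked for, but Jchain had been seen before the list was written. Without it, 4 of 9 are highest, which does not reach that bound, so this source cannot be told apart from others. Of these, Iglv1, Igkc and Iglc2 are immunoglobulin genes themselves, part of the pattern to be explained. That leaves Mzb1 at 1.14 CPM, while Derl3, Tnfrsf17, Eaf2 and Pou2af1 are highest in other libraries. Antibody-secreting cells are thus a hypothesis found and tested on the same library.

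The 2 m non-infarcted library, picked as the highest of 6, gives 83 called genes in limma and 2036 at unadjusted p < 0.05 when set alone against the other 5 of its fit, where the others give 0 to 4 and 151 to 1129. As an arm of 1 library, picked for its count, this only describes it. Older mice at 2 m may be a reason, since the study used mice of different ages. The list of genes known to rise with age lies at percentile 33.1 of random lists, where the top 2.5% had been asked for, and the list of genes known to fall at 92.8, so neither list met the prediction for older mice. Age stays open, since this 1 library also differs from the other non-infarcted libraries in time since stroke and in withdrawal.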
